A study of Homo sapiens with 6 samples.

How the data were processed

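RNA was measured by poly(A)-selected, strand-marking (dUTP) RNA sequencing of 6 libraries from C28/I2 cells, an immortalised human chondrocyte line. Per the labels, 3 libraries came from cells transfected with a negative control siRNA (siNC) and 3 from cells transfected with an siRNA against C9orf72 (siC9orf72), with day 3 given as the treatment. The libraries were sequenced as 150-base pairs, per the labels' protocols. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical.

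Per the submitters' processing notes, the authors used cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR with the genome build GRCh38. The order of the steps, their settings, the annotation release and whether strand was used in counting are not given in the sources used here. The deposited tables held 37777 genes and 152791 transcripts, each with an FPKM value (fragments per kilobase of transcript, scaled to the library) and a count for every library, per the file headers. No column of sample values was left unmatched. No gene was at 0 in all 6 libraries, so genes without any reads were not part of the tables.

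The deposited counts are estimated counts derived from coverage and not tallies of reads. In 15247 transcripts checked, count divided by FPKM and length was constant within each library to 0.468% or better, and gene counts equalled the sum of their transcript counts in at least 99.902% of genes, the largest difference being 2. Among single-transcript genes, low counts favoured multiples of 4: 1047 to 1180 genes per library had a count of 4, against 578 to 697 with a count of 3 and 377 to 408 with a count of 5. This is the pattern that coverage divided by a read length of 75 would give for 150-base pairs, so an estimated count may exceed the number of fragments. For this reason no counting interval or detection limit was drawn from the counts; where genes at 0 in a group are set to 3 estimated counts per library, this is a convention. The totals were 67.3, 59.0 and 58.6 M estimated counts in siNC replicates 1, 2 and 3 and 61.2, 60.7 and 60.6 M in siC9orf72 replicates 1, 2 and 3.

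Genes were compared with edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, glmQLFit and glmQLFTest, TMM scaling factors of 0.987 to 1.02) on the deposited estimated counts, without a replicate block. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05, log2 fold changes are siC9orf72 over siNC, and the standard error (SE) is the log2 fold change divided by the square root of the F statistic. The design had been written for a table of FPKM alone, with limma on log2(FPKM + 1) and genes of mean FPKM of at least 1, and named edgeR as the test should the table hold counts. The same filter was kept and left 12628 genes. C9orf72 and CGAS lay below it and were kept because the design names them, a decision made after their levels were seen, so that 12630 genes were tested. Levels are given as FPKM, mean ± SD over 3 libraries. Transcripts were compared with limma (3.58.1, trend and robust empirical Bayes) on log2(FPKM + 1) for the 28109 transcripts with mean FPKM of at least 1, and fold changes on that scale understate changes of low transcripts. Of the gene identifiers, 35805 were found in GENCODE release 29 (GRCh38), all on the same chromosome, and 83.6% of these shared a start or an end with it. Printed gene coordinates are those of the deposited tables.

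The 32 gene lists (pathways and cell states fitting the study's title and chondrocytes, and markers of other cell types) were fixed before the data were examined, as were the tests, the main alternatives and the rule for named genes. A list was tested when at least 2 members passed the filter, which held for 29. The main list test was camera with a preset correlation of 0.01; camera with an estimated correlation and fry were run beside it. Camera compares a list with all other tested genes. With an estimated correlation, camera tests on the 4 residual degrees of freedom, so a call can be lost without correlation between genes. Fry asks whether a list's own genes move, on balance, one way, and does not compare them with other genes. Camera was also run on 302 KEGG pathways of 10 to 300 tested genes from the deposited annotation, a choice made after the data were seen.

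Named genes were C9orf72, SMCR8, WDR41, STING1, CGAS, TBK1, IRF3, RELA and NFKB1; the 12 raised and the 12 lowered genes with the largest absolute log2 fold change among those with adjusted p under 0.05, a proper gene symbol and all 3 values of one group above all 3 of the other; in each list up to 4 passing members with the smallest adjusted p, or up to 2 with the highest mean FPKM if none passed; and the transcripts of C9orf72. Some results that this rule takes in are not reported here. Other genes are named only where the text says that they were chosen after their values were seen.

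The tests were tested on simulated data first. Counts were drawn for the 12630 genes with 200 of them changed. The comparison of siC9orf72 with siNC recovered 55.2% of genes changed by 0.5 on the log2 scale, 85.1% of those changed by 1 and 98.5% of those changed by 2, with 4.22% false calls. Camera called the shifted list and 0 of 40 unshifted lists. Among the 28109 transcripts, 200 of them changed, the limma test recovered 10% of those changed by 1, with 9.09% false calls. With so few changed, most transcript changes of that size would be missed. Recovery at an adjusted p depends on the share that changes. In the data 6321 genes and 1295 transcripts were called, so these rates need not hold there. Replicates of a group were compared pairwise before averaging: no 2 columns were identical.

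Alternatives fixed before were limma on log2(FPKM + 0.1), limma on log2(FPKM + 1) with FPKM rescaled to equal sums, with median-ratio or quantile scaling, or without trend and robust options, no filter, a minimum mean FPKM of 5, edgeR with DESeq2-type size factors, DESeq2 1.42.0, a replicate block, each library left out in turn, and a 2-fold threshold. Limma on log2(FPKM + 1) without rescaling, the test designed for FPKM alone, was set beside edgeR as an alternative after the data were seen, and edgeR's filterByExpr filter, counts divided by 4, and edgeR on transcript counts were added after the data were seen. In the 3' UTR word test, 1 transcript was taken per gene, the most abundant with at least 50 bases of annotated 3' UTR in GENCODE 29; each of 16145 words of 7 bases present in at least 50 genes was scored by the regression of log2 fold change (limited to 2 in size) on its presence, with cubic terms for 3' UTR length, 3' UTR GC content and mean FPKM. On permuted fold changes, a word given a shift of -0.15 was recovered with an absolute z of 10.9, and without a shift the largest absolute z was 4.54. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.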

Results

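The data were RNA-seq profiles of C28/I2 chondrocytes transfected with a control siRNA (siNC, 3 libraries) or with an siRNA against C9orf72 (siC9orf72, 3 libraries). Library totals ranged from 58.6 to 67.3 M estimated counts. The series title places C9orf72 in osteoarthritis by way of STING and NF-kB signalling, and the single comparison asks which transcripts differ when C9orf72 is lowered. On the first principal component, which held 50.2% of the variance, the 3 siNC libraries lay between -28.9 and -22.0 and the 3 siC9orf72 libraries between 24.5 and 29.5.

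C9orf72 itself, the targeted gene, was lower in each siC9orf72 library than in each siNC library. Its level was 0.918, 1.38 and 1.08 FPKM in siNC replicates 1, 2 and 3 and 0.470, 0.664 and 0.599 FPKM in siC9orf72 replicates 1, 2 and 3. Expression after knockdown was 52.1% of the control (log2 fold change -0.94, SE 0.20, edgeR adjusted p = 0.00273). An exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 libraries allow. The gene (ENSG00000147894) lies on the minus strand of chromosome 9, from 27535640 to 27573819 (GRCh38). Its level was low in both groups, and it lay below 1 FPKM on average. Single C9orf72 transcripts could not be followed, because the estimates moved between isoforms from library to library: the coding transcript ENST00000380003 was listed at 1.44, 0 and 1.93 FPKM in siNC replicates 1, 2 and 3, and the coding transcript ENST00000619707 at 0, 2.25 and 0 FPKM. In the siC9orf72 libraries ENST00000380003 was listed at 0 throughout. The non-coding transcript ENST00000488117 was listed at 0.224 ± 0.0714 FPKM in siNC and 0.623 ± 0.356 FPKM in siC9orf72. In siC9orf72 replicates 1, 2 and 3 it took 66, 260 and 246 of the 213, 295 and 270 estimated counts of the gene. How much of the remaining expression was coding is therefore uncertain. Exact permutation p-values of the C9orf72 transcripts ranged from 0.2 to 1.

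Among the partners of C9orf72 in its complex, WDR41 rose from 7.84 ± 0.321 to 10.1 ± 0.303 FPKM (log2 fold change 0.38, SE 0.05, edgeR adjusted p = 1.43e-04), while SMCR8 stood at 6.49 ± 0.774 in siNC and 5.91 ± 0.176 FPKM in siC9orf72 (log2 fold change -0.12, edgeR adjusted p = 0.269). SMCR8 passed the threshold only without siNC replicate 3 (log2 fold change -0.21, edgeR adjusted p = 0.0191). ATG101, a subunit of the autophagy-starting ULK1 complex, rose by 0.40 on the log2 scale. Of the 7 tested members of the C9orf72 and ULK1 complexes, 2 were higher and 1, C9orf72, was lower. The median (-0.03) and mean (-0.04) of this list lay below 0 while camera placed it above other genes, without passing the threshold (adjusted p = 0.763); without siNC replicate 1 the median was 0.08.

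STING1, the endoplasmic reticulum adaptor that signals after cytosolic DNA is sensed, fell from 8.00 ± 0.533 to 5.30 ± 0.0193 FPKM (log2 fold change -0.57, SE 0.07, edgeR adjusted p = 8.83e-05; chromosome 5, 139475533 to 139482758, minus strand). CGAS, the DNA sensor, was low, at 0.266 ± 0.0394 FPKM in siNC and 0.268 ± 0.0204 FPKM in siC9orf72. The kinase TBK1 (log2 fold change 0.15, edgeR adjusted p = 0.191) and the transcription factor IRF3 (0.03, adjusted p = 0.573) did not pass. TBK1 passed only without siC9orf72 replicate 2 (log2 fold change 0.25, edgeR adjusted p = 0.0465). SURF4, a cargo receptor that returns STING1 to the endoplasmic reticulum, rose from 98.96 ± 1.10 to 148 ± 2.02 FPKM, and RNF5, a ubiquitin ligase acting on STING1, fell from 21.7 ± 0.815 to 12.9 ± 0.343 FPKM. In all, 2 of the 17 tested members of the cGAS-STING pathway were higher and 3 lower, with the same counts adjusted over the list alone (median log2 fold change -0.03, and 0.02 without siNC replicate 1; camera adjusted p = 0.911).

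Interferon-stimulated genes were lower after knockdown nearly throughout. Of 41 tested members, 38 fell and 0 rose, or 40 and 0 adjusted over the list alone, and the median log2 fold change was -0.70 (camera adjusted p = 9.01e-16, and adjusted p = 0.0163 with an estimated correlation). IFIT3, an antiviral effector, fell from 30.9 ± 0.130 to 16.7 ± 0.436 FPKM (log2 fold change -0.87, SE 0.04, edgeR adjusted p = 2.74e-07). IFIT1 fell from 19.5 ± 0.641 to 11.8 ± 0.128 FPKM. STAT2, a transcription factor that carries the interferon signal, fell from 10.4 ± 0.392 to 5.34 ± 0.271 FPKM.

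NF-kB target genes were lower more often than higher. Of 32 tested members, 21 fell and 3 rose (6 rose without siNC replicate 3), with the same counts adjusted over the list alone, and the median log2 fold change was -0.34 (camera adjusted p = 3.04e-04). The list no longer stood apart from other genes with an estimated correlation (adjusted p = 0.389). The adhesion molecule ICAM1 fell from 4.91 ± 0.0719 to 1.21 ± 0.0912 FPKM (log2 fold change -1.995, SE 0.11, edgeR adjusted p = 5.59e-07), the chemokine CCL2 from 11.8 ± 0.927 to 3.96 ± 0.0751 FPKM, the apoptosis inhibitor BIRC3 from 3.47 ± 0.338 to 1.26 ± 0.0917 FPKM and complement C3 from 6.59 ± 0.210 to 3.56 ± 0.282 FPKM. Of the transcription factor subunits, RELA had a log2 fold change of 0.08 (edgeR adjusted p = 0.355), and NFKB1 was higher by 0.16 (SE 0.05, edgeR adjusted p = 0.0231). The NFKB1 call was lost without siNC replicate 2 (log2 fold change 0.15, adjusted p = 0.065), without siC9orf72 replicate 1 (0.15, adjusted p = 0.0786) and without siC9orf72 replicate 3 (0.14, adjusted p = 0.0982), and under all 5 limma settings other than quantile scaling.

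**Figure D1:**
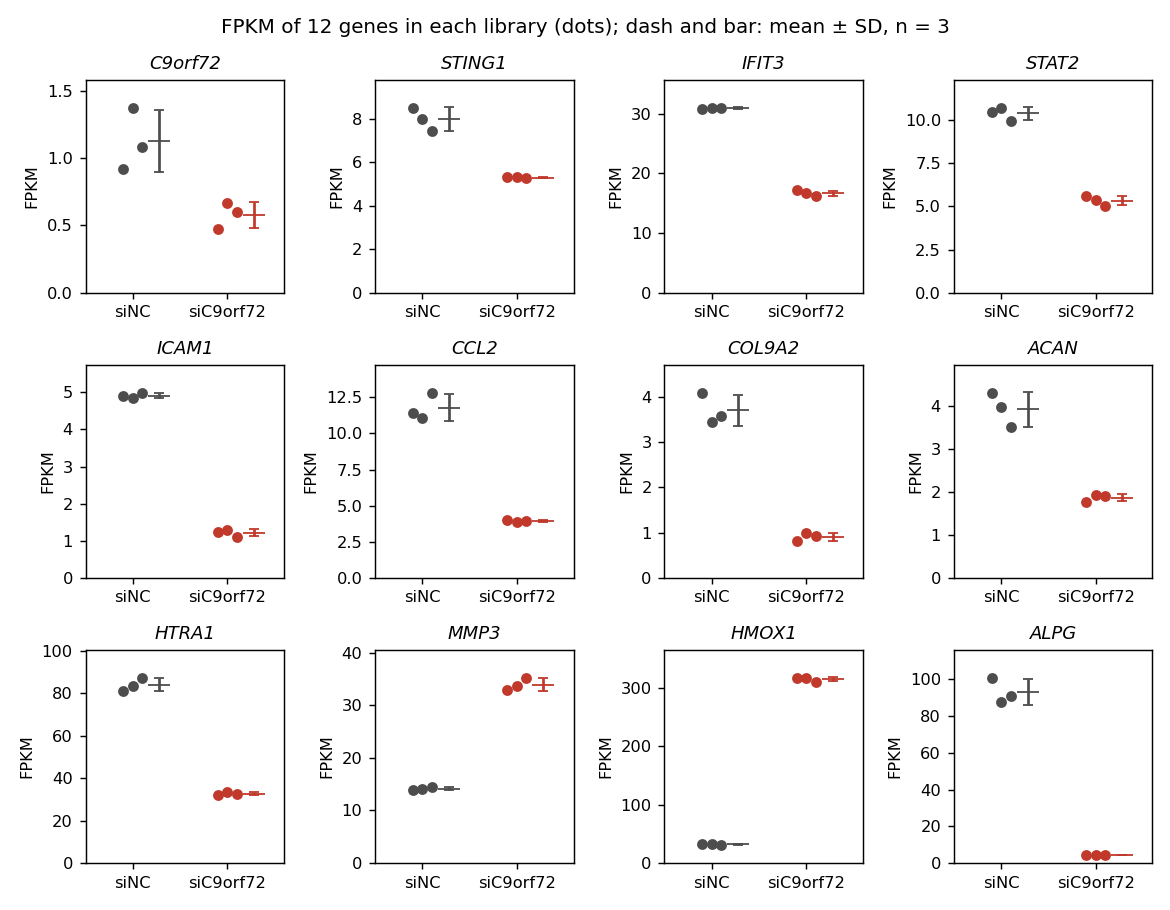
FPKM (linear axes starting at 0) of 12 genes in each of the 3 siNC and 3 siC9orf72 libraries; dots are libraries, and the dash with its bar is the mean ± SD (n = 3). The groups do not overlap for any of the 12 genes, with HMOX1 at 31.8 FPKM in siNC against 315 FPKM in siC9orf72.

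Cartilage matrix genes split. COL9A2, a chain of type IX collagen, fell from 3.71 ± 0.342 to 0.906 ± 0.0816 FPKM (log2 fold change -2.01, SE 0.13, edgeR adjusted p = 1.37e-06), the proteoglycan core protein ACAN (aggrecan) from 3.93 ± 0.406 to 1.86 ± 0.0794 FPKM and the small proteoglycan BGN from 60.6 ± 2.45 to 35.5 ± 2.60 FPKM, whereas CHI3L1, a secreted chitinase-like glycoprotein, rose from 10.7 ± 0.801 to 16.9 ± 0.653 FPKM. Of 38 cartilage genes written down, 10 were expressed highly enough to be tested; 5 fell and 3 rose, with the same counts adjusted over the list alone (median log2 fold change -0.15, camera adjusted p = 0.217). With a minimum mean FPKM of 5 the median was 0.11. It was also 0.11 over the 8 genes without the seed bases TGCATA described below. Of these 8 genes 3 were lower, namely COL9A2, ACAN and BGN, so the falls of these genes do not go with a match in their own 3' UTRs. Over the 2 genes with a 7- or 8-base match it was -0.49. Of 3 tested hypertrophy genes, RUNX2 and VEGFA fell by 0.49 and 0.38 on the log2 scale and MEF2D rose by 0.28 (camera adjusted p = 0.367).

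Matrix-degrading enzymes moved both ways, with 7 of 19 higher and 7 lower. The serine protease HTRA1 fell from 83.9 ± 3.11 to 32.7 ± 0.795 FPKM (log2 fold change -1.34, SE 0.05, edgeR adjusted p = 3.77e-08), and the stromelysin MMP3 rose from 14.2 ± 0.291 to 33.9 ± 1.23 FPKM (log2 fold change 1.28, SE 0.06, edgeR adjusted p = 2.03e-07). Cathepsin B (CTSB) rose from 116 ± 1.58 to 157 ± 2.67 FPKM, and MMP2 fell from 350 ± 17.1 to 251 ± 6.91 FPKM. The median of this list lay above 0 (0.13), its mean below 0 (-0.06) and its camera direction was upward without passing (adjusted p = 0.889). Without siNC replicate 2 the median was -0.03. Among 10 protease inhibitors, 5 rose, SERPINB2 by 1.48 on the log2 scale, and 2 fell, TIMP3 from 192.0 ± 2.63 to 134 ± 2.55 FPKM (median log2 fold change 0.21, camera adjusted p = 0.247); 1 fell without siNC replicate 1 or 3 or siC9orf72 replicate 1 or 2. Fibroblastic matrix genes were split 7 higher and 7 lower of 22, with COL1A2 rising by 0.46 and S100A4 falling by 1.04 on the log2 scale; their median (0.08) and camera direction were above 0 and their mean (-0.0027) below it, without passing (adjusted p = 0.763).

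**Figure D2:**
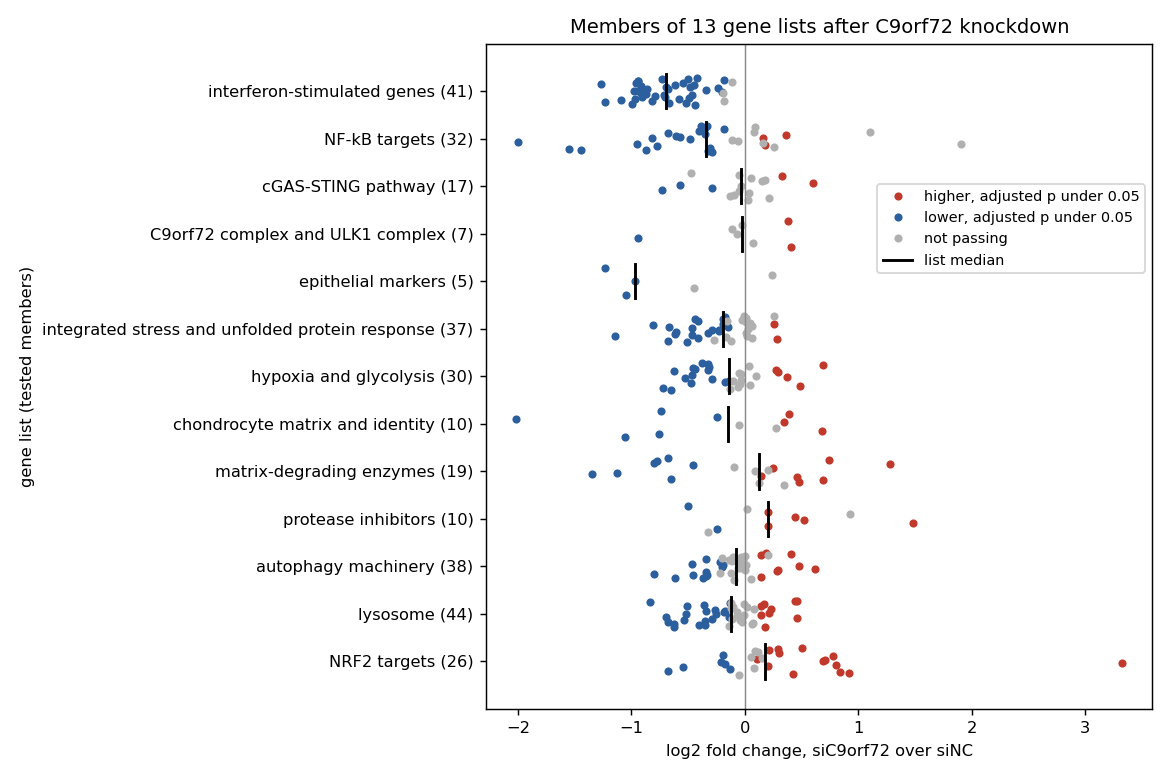
Log2 fold change (siC9orf72 over siNC, horizontal axis) of each tested member of 13 gene lists, with the number of tested members in brackets; dots are genes, coloured by direction where the edgeR adjusted p was under 0.05 and grey otherwise, and the vertical bar is the list median. Of the 41 interferon-stimulated genes, 38 are lower and 0 higher, while matrix-degrading enzymes are spread on both sides of 0.

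The largest single changes lay outside the STING pathway. HMOX1, the heme-degrading enzyme heme oxygenase 1, rose 10.0-fold, from 31.8 ± 1.25 to 315 ± 3.74 FPKM (log2 fold change 3.33, SE 0.05, edgeR adjusted p = 8.59e-11; chromosome 22, 35380361 to 35394214, plus strand). The NRF2 targets to which it belongs, genes of the antioxidant response, included 14 that rose and 6 that fell among 26, or 15 and 6 adjusted over the list alone (median log2 fold change 0.18, camera adjusted p = 1.32e-04, and adjusted p = 0.110 with an estimated correlation). With a minimum mean FPKM of 5 the list did not pass (median 0.08, camera adjusted p = 0.0667). NQO1 and GCLM rose by 0.69 and 0.80 on the log2 scale, and EPHX1 fell by 0.68. TXNIP and ARRDC4, arrestin-family genes, rose by 2.42 and 1.65, and the membrane protein EMP1 rose from 6.42 ± 0.431 to 30.9 ± 1.08 FPKM. At the other end, the alkaline phosphatase ALPG fell from 93.2 ± 6.96 to 4.28 ± 0.149 FPKM (log2 fold change -4.42, SE 0.07, edgeR adjusted p = 1.08e-10). ALPG shares long stretches of sequence with its neighbour ALPP, so its level depends on how shared reads were divided; ALPP, named here after its value was seen, also fell, from 48.8 ± 5.00 to 13.9 ± 0.877 FPKM. The transcription factor EGR1 fell from 33.1 ± 0.721 to 6.89 ± 0.954 FPKM, and the adhesion molecule MCAM by 2.06 on the log2 scale. Also among the 12 most lowered were DIO3, GGT5, RAB17, SCARA5, FXYD6 and PRSS35, with log2 fold changes from -3.04 to -2.07. The 3' UTRs of MCAM, SCARA5 and PRSS35 each hold 1 match to ATGCATA, a word whose presence went with lower fold changes across all genes, and that of TIMP3 holds 1 match to the overlapping word TGCATAA. RASA4 (-2.27) and the pseudogene POM121L9P (-2.45) have near-identical copies and are uncertain. The other most raised genes were ACTL8, MEG9, LRRN4CL, SPRYD3, BBOF1, STK40, DCBLD1 and GAPLINC, with log2 fold changes from 1.61 to 2.53.

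Over all 12630 tested genes, 3108 were higher and 3213 lower after knockdown (edgeR adjusted p under 0.05), 50.0% of the genes tested. Most changes were small: 127 genes were higher and 306 lower by at least 2-fold. The 3 values of one group lay above all 3 of the other in 58.4% of genes, where chance gives 10%. At the transcript level, limma called 1295 of 28109 transcripts, 631 higher and 664 lower. They came from 1206 genes, of which 1200 were tested as genes and 1130 were also called as genes. Leaving out 1 library at a time, siNC or siC9orf72, lowered the transcript count to between 220 and 504, 21 transcripts passed when low values were not filtered out, and 0 with a replicate block (4740 at an unadjusted p under 0.05).

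Markers of other cell types were mostly low, and several were lower after knockdown. Among epithelial markers, KRT8 fell from 116 ± 4.11 to 48.5 ± 1.85 FPKM, KRT18 from 130 ± 4.85 to 65.8 ± 0.801 FPKM and the tight junction gene CLDN4 from 8.39 ± 0.490 to 4.02 ± 0.637 FPKM; 3 of 5 tested members fell and 0 rose (median log2 fold change -0.97, camera adjusted p = 4.38e-05, and adjusted p = 0.110 with an estimated correlation). Epithelial markers did not pass in limma with a pseudocount of 0.1 (adjusted p = 0.054) or with median-ratio scaling (adjusted p = 0.058). The muscle genes DES, TNNT1 and MYH2 all fell, by 0.40, 0.49 and 0.44 on the log2 scale (camera adjusted p = 0.0751, and 0.0386 without siNC replicate 2). Of 3 tested leukocyte genes, CD68 rose from 29.9 ± 1.3 to 39.4 ± 1.54 FPKM, CSF1R fell by 0.37 and LYZ, very uneven between libraries at 21.9 ± 17.6 FPKM in siNC and 3.96 ± 3.5 FPKM in siC9orf72, had an edgeR adjusted p of 0.0434; the median (-0.37) and mean (-0.80) of this list lay below 0 and its camera direction above it (adjusted p = 0.889). LYZ lost its call in 14 of 19 other settings, with an adjusted p of up to 0.375, among them without siNC replicate 2 (adjusted p = 0.128), without siNC replicate 3 (0.112), without siC9orf72 replicate 2 (0.120) and without siC9orf72 replicate 3 (0.124), and CSF1R lost its call in 4 of 18, among them without siNC replicate 1 (0.0536) and without siC9orf72 replicate 1 (0.059). PDPN fell by 0.73 among 3 tested synovial lining genes (camera adjusted p = 0.763). Of the endothelial markers and of the adipocyte markers, 1 each was expressed highly enough: VWF fell from 1.96 ± 0.0193 to 1.10 ± 0.108 FPKM and CEBPA from 1.81 ± 0.0733 to 1.24 ± 0.122 FPKM. CEBPA lost its call in 6 of 18 other settings, among them without siNC replicate 1 (adjusted p = 0.0549), without siNC replicate 3 (0.069), without siC9orf72 replicate 1 (0.0652) and without siC9orf72 replicate 3 (0.0879).

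Camera called 6 of the 29 tested lists, and 1 of them, the interferon-stimulated genes, held with an estimated correlation. The other 5 were NF-kB targets, NRF2 targets, epithelial markers, the integrated stress and unfolded protein responses, and hypoxia and glycolysis. Their estimated correlations were 0.134, -0.0238, 0.0384, -0.00127 and 0.00552 in that order, against the preset 0.01. Correlation between genes thus does not account for the lost calls of the lists under 0.01. Fry, which asks only whether a list's own genes moved one way, called 20.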

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

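Limma on log2(FPKM + 1) without rescaling, as an alternative to edgeR, and edgeR's filterByExpr filter, counts divided by 4 and edgeR on transcript counts were chosen after the data were seen. Across 19 other settings for the genes, 0 genes were called in the direction opposite to the main setting. Without 1 library, siNC or siC9orf72, 2619 to 2996 genes were higher and 2731 to 2971 lower. With a minimum mean FPKM of 5, 1947 were higher and 1968 lower of 6802 tested, and with a 2-fold threshold 127 were higher and 306 lower. A replicate block gave 2986 higher and 3066 lower genes. The replicate numbers showed no sign of pairing. Correlations between libraries of the same number were -0.243, -0.048 and -0.159 for numbers 1, 2 and 3, and no siNC library correlated best with its own number. With 3 libraries per group, pairing cannot be excluded. The 1295 changed transcripts became 21 in limma without a filter, where 152791 transcripts were tested (9350 at an unadjusted p under 0.05). With the replicate block limma called 0 (4740 at an unadjusted p under 0.05), and edgeR without a block called 1263. The cause was tested for neither drop. Without 1 library, 220 (siC9orf72 replicate 1) to 504 (siNC replicate 1) transcripts passed, with fewer libraries to test on. The interferon-stimulated genes passed in all 21 other settings, with medians of -0.71 to -0.51 and adjusted p of 0.0163 or less. NF-kB targets had medians of -0.35 to -0.27 and lost their call with an estimated correlation alone (median -0.34, adjusted p = 0.389). That option allows for genes moving together (estimated correlation 0.134 for this list) and also tests on 4 residual degrees of freedom. Cartilage genes passed in fry alone (median -0.15, adjusted p = 0.00597), which does not compare them with other genes; their median ranged from -0.49 to 0.11. STING1 had log2 fold changes of -0.62 to -0.49 and passed in all 19 settings, as did C9orf72 (-1.07 to -0.33). The C9orf72 range takes in limma on log2(FPKM + 1), whose fold changes understate those of genes as low as C9orf72. Among named genes, 2468 of the values kept direction and call, 45 lost the call, 2 gained it and 1 reversed: MT-ND4 had a log2 fold change of 0.0333 under quantile scaling against -0.15, and the cause was not tested. Among gene lists, 570 kept theirs, 31 gained and 8 lost a call. The estimated counts may exceed fragment numbers, so no detection limit is given for genes listed at 0.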

Other observations

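Of 37 tested genes of the integrated stress and unfolded protein responses, 20 fell and 2 rose, or 21 and 2 adjusted over the list alone (median log2 fold change -0.19, camera adjusted p = 0.00313, and adjusted p = 0.114 with an estimated correlation), among them CHAC1, which degrades glutathione, from 10.2 ± 0.825 to 4.54 ± 0.463 FPKM, and PHGDH, the enzyme that opens serine synthesis, from 8.96 ± 0.204 to 5.05 ± 0.176 FPKM. Of 30 hypoxia and glycolysis genes, 15 fell and 5 rose, or 16 and 5 adjusted over the list alone (median -0.13, camera adjusted p = 0.0209, and adjusted p = 0.230 with an estimated correlation). The median was -0.08 over the 22 without the seed bases TGCATA described below and -0.46 over the 4 with a 7- or 8-base match. Lactate dehydrogenase LDHA fell from 318 ± 7.65 to 218 ± 1.27 FPKM. Of 44 lysosome genes 20 fell and 9 rose (camera adjusted p = 0.110), with the membrane protein SCARB2 lower by a log2 fold change of -0.83. Of 38 autophagy genes 12 fell and 8 rose (adjusted p = 0.596; 5 rose without siC9orf72 replicate 1 or 3), with BECN1 at 0.62 and ATG12 at -0.61. The 3' UTRs of SCARB2 and ATG12 each hold 2 of the seed matches described below, and that of LDHA holds 1. Those of CHAC1, PHGDH and BECN1 hold none. Of 24 cholesterol synthesis genes 10 fell and 4 rose (adjusted p = 0.217), with INSIG1 at -0.72 and STARD4 at -0.55. Of 58 nuclear OXPHOS genes 17 fell and 6 rose (adjusted p = 0.247), but 10 fell without siC9orf72 replicate 2 and 3 rose without siC9orf72 replicate 3, and of 13 mitochondrial genome genes 4 fell and 2 rose (adjusted p = 0.889), MT-CO1 at -0.11. The number of mitochondrial genome genes that rose was 0 without siNC replicate 1, siC9orf72 replicate 1 or siC9orf72 replicate 2, 4 without siNC replicate 2 and 1 without siNC replicate 3. In limma with quantile scaling and in edgeR without a filter, 0 of them rose and 0 fell, and MT-CO1 lost its call in 4 of 19 other settings, with log2 fold changes from -0.15 to 0. Of 302 KEGG pathways, tested after the data were seen, camera called 4, all lower: thiamine metabolism (adjusted p = 2.11e-05) and folate biosynthesis (0.00204), both led by ALPG and ALPP, Staphylococcus aureus infection (4.82e-04), led by KRT18 and ICAM1, and rheumatoid arthritis (0.0269), in which 23 of 41 genes fell and 5 rose. All 4 had an adjusted p of 0.849 with an estimated correlation.

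Of 29 p53 targets 11 fell and 6 rose (camera adjusted p = 0.124; median -0.15 over all, -0.0049 over the 21 without the seed bases TGCATA described below and -1.17 over the 4 with a 7- or 8-base match); the cell cycle inhibitor CDKN1A fell from 64.8 ± 3.01 to 39.5 ± 0.900 FPKM, and PMAIP1, a pro-apoptotic BCL2-family gene, rose from 51.1 ± 0.122 to 86.7 ± 4.31 FPKM. Of 41 S phase genes 11 rose and 2 fell (adjusted p = 0.426; 1 fell without siNC replicate 3 or siC9orf72 replicate 1 or 2), and of 51 G2/M genes 17 rose and 2 fell, or 7 and 1 adjusted over the list alone (adjusted p = 0.217), with TUBB4B at a log2 fold change of 0.44. The G2/M counts depended on single libraries: 10 rose without siNC replicate 3 and 7, 8 and 11 without siC9orf72 replicates 1, 2 and 3, and 1 fell without siNC replicate 2 or any siC9orf72 replicate. Of 78 ribosomal protein genes 16 rose and 3 fell, or 6 and 2 adjusted over the list alone (median 0.11, adjusted p = 0.136). The ribosomal count that rose was 54 without siNC replicate 3 (adjusted p = 3.29e-04), 8 without siNC replicate 2, and 8, 10 and 6 without siC9orf72 replicates 1, 2 and 3, and the list passed in 8 of 21 other settings. Of 24 senescence genes 7 rose and 8 fell (adjusted p = 0.763), with IGFBP3, which binds insulin-like growth factors, at 1.45 and the TNF receptor TNFRSF1A at -0.96. Of 25 TGF-beta targets 8 rose and 9 fell (adjusted p = 0.723; 5 rose without siC9orf72 replicate 3), with N-cadherin (CDH2) at 1.05 and ID3 at -0.81. TNFRSF1A and ID3 each have 1 seed match, and CDKN1A, PMAIP1 and CDH2 have none. Of 18 immediate-early genes 6 rose and 7 fell (median -0.02, adjusted p = 0.217; without siC9orf72 replicate 1 the median was 0.01 and the adjusted p 0.029), with FOS at -1.60 and FOSL1 at 0.81. Of 12 histone genes 2 rose and 5 fell (adjusted p = 0.723; 3 fell without siNC replicate 1 or 3 or siC9orf72 replicate 2 or 3), with H2BC21 at -0.81. H2AC6 has 1 seed match and rose, by 0.65 on the log2 scale.

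The tests of library depth, genomic DNA and unspliced RNA were chosen after the result was seen. The 6 bases TGCATA, by which gene lists were split, came from the word test on these same fold changes. A lower median among matched members was thus favoured in advance. It was seen in most lists, but not in NF-kB targets, NRF2 targets, protease inhibitors or epithelial markers. For NF-kB targets the median was -0.32 over the 3 members with a 7- or 8-base match and -0.35 over the 27 without the 6 bases. For NRF2 targets it was 0.36 over 2 members and 0.18 over 22. The interferon-stimulated genes were lower by a median of -0.70. The values argue against a trend on GC content, transcript length and level as the whole cause, since removing it left a median of -0.6319 over the 41 members, and against siRNA seed matches in the genes' own 3' UTRs, since the 30 members lacking the 6 bases TGCATA had a median of -0.6225. A response of the siNC cells to the control siRNA stays open: the summed FPKM of 6 interferon genes was 6.68 on average in siNC, between 6.52 and 6.88, and 4.31 in siC9orf72, between 3.63 and 5.32. Less interferon signalling after loss of C9orf72, with STING1 lower, would give the same difference, and there is no untransfected library to separate them.

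Genes of low abundance were lower more often than higher: among 9323 genes of mean FPKM under 1 that pass filterByExpr, 838 fell and 282 rose, with a median of -0.15 over all of them and of -1.31 over the lower ones, the latter the same with the 36 genes at 0 in siC9orf72 set to 3 estimated counts per library. Depth is argued against, since the 2 siNC libraries with totals under those of every siC9orf72 library held at least 29368 genes above 0 and the siC9orf72 libraries at most 28602. Genomic DNA in the siNC libraries as the cause of the calls is argued against by 239 olfactory receptor genes and pseudogenes of mean FPKM under 0.5, whose summed counts had a log2 ratio (siC9orf72 over siNC) of -0.0451 with a spread of 0.0991; the 119 coding ones among them had 0.05, and 129 coding ones of any level -0.21, mostly from 10 genes of mean FPKM of at least 0.5 (-0.26); all lie above the -1.31 of the lowered genes, but they lie on both sides of the -0.15 over all, and a share of DNA in that small shift stays open. Unspliced RNA stays open: retained-intron transcripts took 6.91% to 7.5% of counts in siNC (mean 7.23%) and 6.97% to 7.04% in siC9orf72 (mean 7.00%), the ranges overlapping through 1 siNC library. An effect of the knockdown stays open too, as untested.

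With 6321 of 12630 genes changed, the 10 splits of 6 libraries are too few for a share under 0.05: the real split, 1 of 10 with as many genes, gave 6321 in edgeR and the highest other 0 (97 to 148 at an unadjusted p under 0.05). Across 3' UTRs of 10950 genes, the 7-base word ATGCATA stood furthest from 0 of 16145 words (z = -19.3). It was followed by words that share TGCATA with it (TGCATAA at -17.1, TGCATAT at -14.7 and TTGCATA at -12.6). The word furthest on the other side, TCGGAGA, had z = 6.14. The longer the match, the lower the median log2 fold change. It was -0.28 in 305 genes with both overlapping words (8 bases), and -0.20 and -0.14 in 759 and 537 genes with ATGCATA or TGCATAA alone. It was -0.04 in 1330 genes with TGCATA alone (6 bases) and 0.04 in 8019 with none. Unlike the z values, these medians were not adjusted for 3' UTR length, GC content or level. The match types were built from words found on the same fold changes. ATGCATA occurs at 1 place (chromosome 9, 27566679 to 27566685, minus strand) in 6 annotated C9orf72 transcripts, where 28% of all words occur. A 7- or 8-base match was held by 25.2% of lowered, 7.27% of raised and 12.7% of not passing genes with a 3' UTR. A seed of the siRNA against C9orf72 is thus a candidate explanation for part of the lowered genes. Yet 2208 of 2952 lowered genes with a 3' UTR have no 7- or 8-base match, and 403 of these hold the 6 bases alone. TNFRSF1A (-0.96), the interferon gamma receptor IFNGR1 (-1.01) and the HMOX1 repressor BACH1 (-0.51) were lower and have matches, IFNGR1 and BACH1 being named after their values were seen, and a further hypothesis, untested, is that these may carry such an effect to interferon-stimulated genes, NF-kB targets and HMOX1. The siRNA sequence is not given in the sources used here, and 1 siRNA cannot separate such off-target effects from loss of C9orf72.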
